A study of Mus musculus with 47 samples.

How the data were processed

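Single granulocyte-monocyte progenitors (GMP) were sorted from bone marrow of C57BL/6 mice as lineage-negative, CD117-positive, Sca-1-negative, CD16/32-positive and CD34-positive cells, and were labelled as lacking both Gfi1 and Irf8. Per the labels' protocols, cells were separated on the Fluidigm C1 system, cDNA was made with SMARTer chemistry, and libraries were made with Nextera XT, a kit that does not mark the strand. The submitters' processing notes name Bowtie2, RSEM and the mouse build mm9, without versions. The annotation and any filter on cells or genes are not given in the sources used here.

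The authors deposited 1 table of log2 values with 23955 gene symbols and 47 columns, each column a cell. The deposited values were read as log2(TPM + 1), where TPM is transcript abundance scaled to the same total in every cell, because raising 2 to each value and subtracting 1 gave the total that TPM has by definition in all 47 columns. TPM keeps no sequencing depth, so the depth per cell is unknown and no interval that needs read counts is given. The number of genes detected per cell was used as a stand-in for capture and depth. Of the 47 columns, 41 were matched to 1 sample by the name of the cell, and 6 were matched to the group only. All columns were used.

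The labels name no animal, so the 47 cells were treated as 1 sample and cells were not used as replicates. No p-value, standard error or test was computed from cells. Counts of cells carry exact Clopper-Pearson 95% intervals, which cover the counting of these cells only. For a count of 0 in 47 cells that interval reaches 7.55%, while the simpler limit of 3 cells of the total is 6.38%. An exact 0 in this table can be a failed estimate, since Tbp, a general transcription factor gene, was listed at 0 in 24 cells and Hprt in 4. A gene is therefore described as listed at 0, not as absent.

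A gene was called detected at TPM 1 or more. Gene lists were fixed before the data were examined: the targeted genes, genes of the sorted and other stained surface proteins, primary granule, late granule, monocyte, stem and multipotent, megakaryocyte and erythroid, basophil, mast cell and eosinophil, dendritic, lymphoid, stromal, transcription factor, Gfi1-repressed, S phase, G2 and M phase, housekeeping, stress, interferon and sex-linked genes. The primary granule list also holds promyelocyte genes, and the late granule list also holds later neutrophil genes. Ly6g was the 1 listed gene without a row of its own. The level of a list in a cell was the mean of log2(TPM + 1) over its members. Coordination was the median pairwise Spearman rho across cells, within a list or between lists without shared genes. It is given with its percentile among 10000 random lists of the same size, drawn from windows of 100 genes of like mean level. Random lists were not matched on the correlation among their own members. Percentiles between lists of correlated genes may therefore be too extreme. Percentiles in the outer 2.5 at either end are described as outside the random range, which is a description of these cells and not a test. Partial rank correlations held the number of genes detected constant.

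Cells were clustered by Ward linkage on 10 principal components of the 500 genes with the largest variance above a lowess trend (span 0.2), among genes detected in at least 5 cells. Between 2 and 5 clusters were allowed and the mean silhouette chose the number, set beside 100 data sets with each gene permuted over cells. No doublet caller was run, since a C1 plate of 47 cells is too small for one. The text names list members, the 10 genes with the highest mean, the 10 with the largest excess variance, the 5 highest and 5 lowest genes by rho with the primary granule minus monocyte difference, and up to 10 leading genes per cluster. Genes named outside that rule are marked as such. Reads may be split between near-identical genes, so values of Ly6a, Ly6c1, Ly6c2 and Ly6i, of Fcgr2b and Fcgr3, and of Chil3 are uncertain to that extent.

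The steps were tested on simulated data, made by shuffling the values of 8890 genes over cells. A planted list of 12 correlated genes lay at percentile 100, and 1 of 40 lists without a planted relation lay outside the random range. Each gene was shuffled on its own, so all other relations between genes were removed. Percentiles between lists were not simulated. With planted groups of cells, 2 clusters were found with an adjusted Rand index of 1. Of the genes shifted by 2 on the log2 scale, 39.0% were among the variable genes, and of those shifted by 4, 81.0%.

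Alternatives covered the detection minimum, the pseudocount, the members and summary of a list, the cells kept, the scaling, the correlation used and the clustering. A count of cells was taken to have moved when it left the exact interval of the reported one, a level or difference when it changed by 1 SD across cells or more, and a median rho when it changed by 1 SD of the random lists or more. The reference transcripts at hand (GENCODE M21 on GRCm38) are of another build than mm9, so no coordinates are given and they were used only to count shared sequence stretches. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, scikit-learn 1.9.0 and matplotlib 3.10.9.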

Results

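The series holds 47 single bone marrow progenitors in 1 group, sorted as GMP and labelled Gfi1-/- Irf8-/-. Gfi1 encodes a repressor needed for neutrophil development, and Irf8 encodes a factor needed for monocyte and dendritic cell development. The series asks which lineage genes progenitors with this label use. No control genotype was analysed here, so values are described within these cells. A median of 4314 genes was detected per cell (quartiles 3927.5 and 4814.5), from 2582 in cell B1 to 5775 in cell E7. Over all cells 11708 genes were detected, and 469 in every cell. The 10 highest genes of a cell held a median of 13.9% of its TPM (range 9.65% to 32.5%).

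Transcripts of both targeted genes were present in the cells labelled Gfi1-/- Irf8-/-. Irf8 was detected in 47 of 47 cells (exact 95% interval 92.5% to 100%) at a median of 808 TPM, with quartiles of 556 and 1240 TPM. Gfi1 was detected in 39 of 47 cells (83.0%, interval 69.2% to 92.4%) at a median of 195 TPM, and was listed at 0 in 5 cells. The median of Irf8 stood at percentile 98.5 of the genes detected in any cell and that of Gfi1 at 94.9. Across cells the 2 genes had a rho of -0.15 (r = -0.23). A value per gene does not show which exons the reads covered, so it checks the genotype labels only in part.

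**Figure D1:**
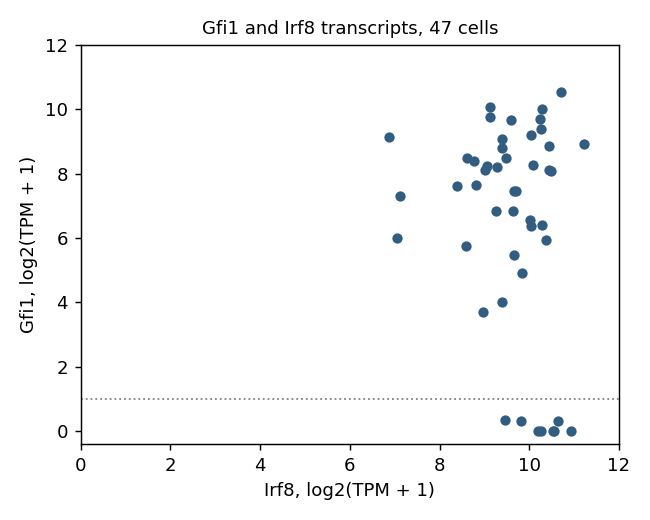
Gfi1 against Irf8 in 47 cells, each point a cell, both axes in log2(TPM + 1), with the detection minimum for Gfi1 dotted. Irf8 was detected in 47 cells, and 8 cells lay below the Gfi1 minimum.

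Genes of the surface proteins that the sort required were detected in most cells. Fcgr3, which encodes an Fc receptor bound by the CD16/32 antibody, was detected in 47 cells at a median of 1341 TPM. Cd34 was detected in 46 cells, Kit (CD117) in 41 and Fcgr2b in 33. At least 3 of these 4 genes were detected in 45 of 47 cells (95.7%, interval 85.5% to 99.5%). Of the excluded proteins, the genes Cd3e, Cd4, Cd19 and Gypa were listed at 0 in all cells, Cd8a was detected in 1 cell, and Itgam (CD11b) in 9. Ly6a, which encodes Sca-1, was detected in 47 cells at a median of 39.3 TPM, although the sort took Sca-1-negative cells. Ly6a shares sequence with its Ly6c relatives, 26.8% of its 25-base stretches being found in Ly6c1 or Ly6c2. Of the other stained proteins, Csf1r was detected in 29 cells, Flt3 in 14, Siglec5 in 9 and Ccr3 in 0.

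The primary granule list, which also holds promyelocyte genes, was the highest lineage list in every cell. Of its 10 members, 9 were detected in all 47 cells. The protease gene Elane and the peroxidase gene Mpo were highest, with medians of 27749 and 27432 TPM, followed by Gstm1, a glutathione transferase gene, at 4762 TPM and the protease genes Prtn3 at 3653 and Ctsg at 2230. Fcnb, a ficolin gene, was detected in only 20 cells. The level of the list had a median of 10.59 (quartiles 10.30 and 11.07) on the log2(TPM + 1) scale. With only members detected in 5 cells or more, the lymphoid list, then Nkg7 alone, had a higher median level of 11.52.

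Late granule genes varied far more between cells, with a median level of 2.96 (quartiles 2.33 and 3.96). Mmp8, a neutrophil collagenase gene, was detected in all cells at a median of 1044 TPM. S100a8, which encodes a subunit of calprotectin, was also detected in all cells, from 3.70 TPM to 148490 TPM in cell D2. Its partner S100a9 was detected in 28 cells, and both genes together held 23.4% of the TPM of cell D2 against a median of 0.511% over cells. Lcn2 was detected in 42 cells, Chil3 in 26 and Cebpe, a regulator of late granule genes, in 19. Cd177 was detected in 3 cells and Camp and Ngp in 1 each, while Ltf, Itgb2l and Retnlg were listed at 0 in all cells.

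Monocyte genes had a median level of 3.96 (quartiles 3.73 and 4.45). Ly6c2 (median 3612 TPM) and Ms4a6c (294 TPM) were detected in all cells. Ccr2, the receptor for Ccl2, was detected in 45 cells, F13a1 and Tifab in 44, Ctss in 35, and Csf1r and Zeb2 in 29. Mpeg1 was detected in 13 cells, Klf4 in 12, Fn1 in 7, Cx3cr1 in 4 and Ly86 in 1, while S100a4 was listed at 0 in all cells.

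Lists of other lineages were low. Dendritic genes had a median level of 1.31, with Cst3 in 47 cells, Tcf4 in 42, Bst2 in 18, and Id2 and H2-Ab1 in 13 each. H2-Ab1, a class II gene, reached 263 TPM, while Cd74, H2-Aa, Irf4 and Itgax were listed at 0 in all cells. Stem and multipotent genes had a median level of 0.62, with Lmo2 in 45 cells, Flt3 in 14, Cd27 in 10, Hoxa9 in 8 and Meis1 in 7. Basophil, mast cell and eosinophil genes also had 0.62, with Hdc, which makes histamine, in 35 cells and Mcpt8 in 14. Lymphoid genes had 0.97, almost all from Nkg7, detected in 47 cells at a median of 2937 TPM, with 9 of 12 members detected in none. Stromal genes had 0.80, from Lepr in 42 cells at a median of 2.88 TPM and Pecam1 in 22. Megakaryocyte and erythroid genes had 0.22, with 10 of 15 members detected in none, and only Tfrc (28 cells) in 5 cells or more.

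**Figure D2:**
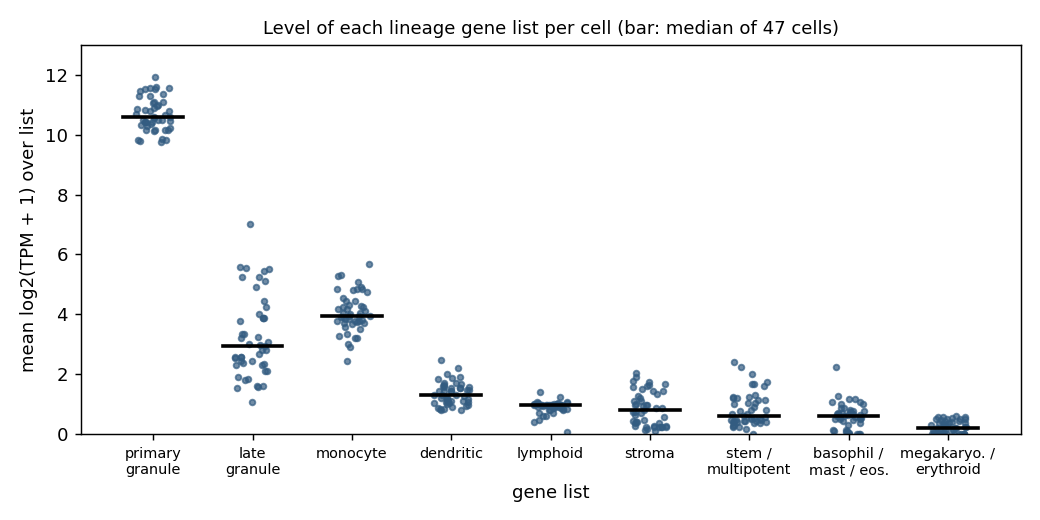
Level of 9 lineage lists per cell, as the mean log2(TPM + 1) over the members of each list, with points for the 47 cells and a bar at their median. Primary granule genes had a median of 10.59, monocyte genes 3.96 and late granule genes 2.96.

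Among transcription factors, Myb was detected in all cells at a median of 161 TPM. Myc was detected in 33 cells, Spi1 in 30, Runx1 in 29 and Cebpa in 25, whereas Irf5 was detected in 2 cells and Egr2 in 1. The list had a median level of 2.27. Of 7 genes known to be repressed by Gfi1, Id2 was detected in 13 cells, Hoxa9 in 8, Meis1 in 7, Gfi1b in 3, and Egr2 and Pbx1 in 1 each. Csf1 stayed below the minimum in all cells, and the list had a median level of 0.56.

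Within a cell, primary granule genes lay above monocyte genes in 47 of 47 cells, by a median of 6.77 (range 4.77 to 8.62) on the log2(TPM + 1) scale. Late granule genes lay above monocyte genes in 15 of 47 cells (31.9%, interval 19.1% to 47.1%), with a median difference of -1.27 (quartiles -2.08 and 0.54). That sign depended on the members used. With only members detected in 5 cells or more, the median difference was 0.36 and 31 cells lay above 0. Without S100a8 and S100a9, chosen after seeing the data, 3 cells did.

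Members of the granule and monocyte lists were detected together in single cells. At least 3 primary granule and 3 monocyte genes were detected in 47 of 47 cells (interval 92.5% to 100%), and at least 3 late granule and 3 monocyte genes in 46 (97.9%, interval 88.7% to 99.9%). With no association between the lists, 47 and 46 cells were likewise expected. All 47 cells passed for the monocyte list, so the expected and observed counts had to be equal. These counts therefore cannot show an association or its absence. No doublet caller was run. Asking for 5 members of each list left 47 and 26 cells. Primary granule genes were found with dendritic genes in 31 cells, with stem and multipotent genes in 13, with basophil, mast cell and eosinophil genes in 5, and with megakaryocyte and erythroid, lymphoid or stromal genes in 0. Because every cell passed for the primary granule list, each of these counts equals that of the other list alone.

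Across cells, late granule genes ran with primary granule genes and against monocyte genes. Late granule genes had a median rho of 0.20 with one another (percentile 100 of random lists) and 0.10 with primary granule genes (percentile 99.99). Against monocyte genes their median rho was -0.071, lower than in any of 10000 random lists. Those lists were matched on mean level and not on correlation within a list, so this rank may be too extreme. The levels of the late granule and monocyte lists had a rho of -0.39 (r = -0.37), and r was -0.39 without the 2 cells farthest from the median. The levels of the primary and late granule lists had a rho of 0.65 (r = 0.68, and 0.60 without 2 cells). These are among 44 medians within or between lists and 153 relations of levels that were computed.

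Primary granule and monocyte genes had a median rho of -0.032, just outside the random range at percentile 2.45. It lay inside the range at 7.02 with only members detected in 5 cells or more and at 11.5 with the number of genes detected held constant. Primary granule genes correlated with one another at a median rho of 0.16 (percentile 99.3), but at percentile 95.02 with Pearson's r (median 0.12). After rescaling, chosen after seeing the data, the median rho was 0.30 (percentile 99.72). Monocyte genes did not stand apart, with a median rho of 0.024 among themselves (percentile 68.3).

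**Figure D3:**
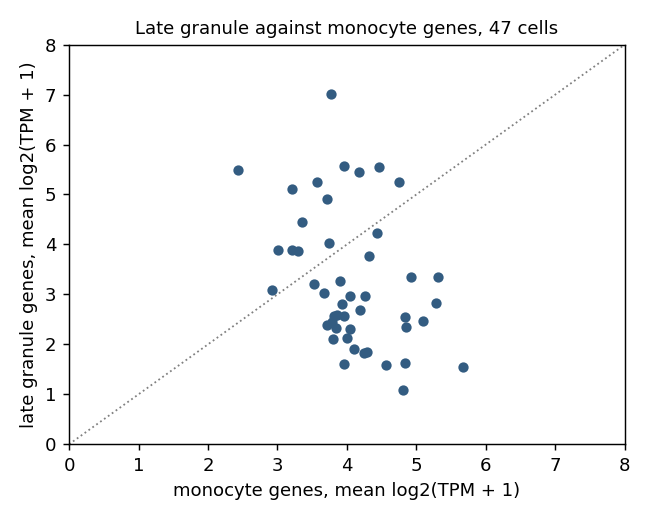
Level of late granule genes against that of monocyte genes in 47 cells, both as mean log2(TPM + 1), each point a cell, with equality dotted. The rho was -0.39, and 15 cells lay above the line.

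Outside the lists, the genes with the highest rho to the primary granule minus monocyte difference were Srgn (0.59), which encodes a granule proteoglycan, Hmgn2 (0.58), Slc40a1 (0.58), Anxa1 (0.57) and Tmsb4x (0.54). Those with the lowest were Hsp90ab1 (-0.61), Dpysl2 (-0.57), Ifitm3 (-0.57), Lgals1 (-0.56) and Slc39a6 (-0.55). Each was picked as an extreme among many genes, with no test. The difference itself had a rho of -0.51 with the S phase level and -0.34 with the number of genes detected. Neither was held constant for these genes.

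Cell cycle genes varied widely. At least 10 of 21 S phase genes were detected in 39 of 47 cells (83.0%, interval 69.2% to 92.4%), and at least 10 of 20 G2 and M phase genes in 20 cells (42.6%, interval 28.3% to 57.8%). Both held in 18 cells and neither in 6. The S phase list, which includes the replicative helicase genes Mcm2 to Mcm7, had a median level of 5.16 and the G2 and M phase list 2.02. Genes correlated within each list, at a median rho of 0.34 for S phase and 0.43 for G2 and M phase, both at percentile 100. S phase genes ran with monocyte genes (median rho 0.10, percentile 100) and against primary granule genes (-0.14, below all random lists). Here too the random lists were not matched on correlation within a list. The levels of the S phase and monocyte lists had a rho of 0.46 (r = 0.44, and 0.45 without 2 cells), and 0.32 with the number of genes detected held constant. That number itself had a rho of 0.54 with the S phase level, at percentile 24.2 of random lists, and 0.39 with the monocyte level, at percentile 40. It had a lower rho than most random lists with the late granule level (-0.25, percentile 0), the stem and multipotent level (-0.098, percentile 0.39) and the primary granule level (-0.14, percentile 2.05). The same held for the Gfi1-repressed level (-0.13, percentile 0.64), the transcription factor level (0.17, percentile 0.75) and the stress level (0.049, percentile 2.1).

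**Figure D4:**
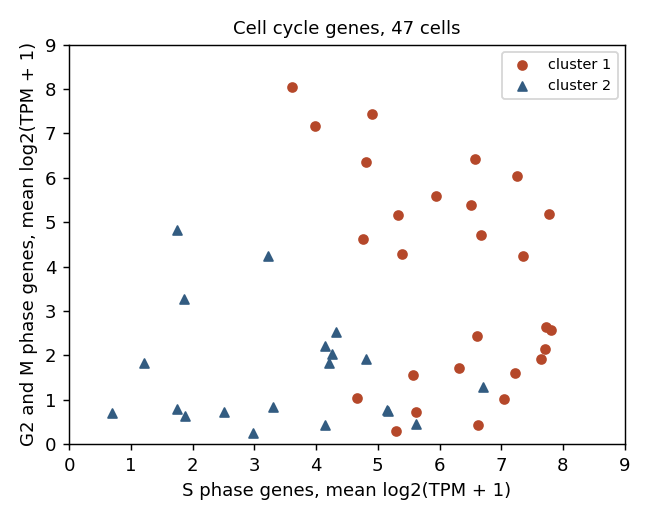
Level of G2 and M phase genes against that of S phase genes in 47 cells, both as mean log2(TPM + 1), with circles for the 27 cells of cluster 1 and triangles for the 20 of cluster 2. Cluster 1 had median levels of 6.51 for S phase and 4.25 for G2 and M phase genes, and cluster 2 had 3.72 and 1.06.

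Clustering parted the cells into 27 and 20, with a silhouette of 0.156 against at most 0.119 in permuted data. Permuting each gene removed all relations between genes, so this comparison cannot tell separate groups from a gradient. Cluster 1 was led by Asf1b, Tk1, Rrm2, Tcf19, Rfc4, Top2a, Pbk, Fignl1, Uba2 and Kpna2, of which Rrm2 is in the S phase list and Top2a in the G2 and M phase list. Cluster 2 was led by S100a9, Hnmt, Cdc40, Ncam1, Rgs18, Casp4, S100a8, Tm2d3, Tgoln1 and Ociad1, of which S100a9 and S100a8 are in the late granule list. Neither had 3 lineage markers among its leading genes, so both stay numbered. The first principal component held 8.86% of the variance. Its rho was -0.85 with the number of genes detected, -0.73 with the S phase level and -0.68 with the G2 and M phase level. Median numbers of genes detected were 4684 and 3939 in clusters 1 and 2. Which cells fell together depended on some settings and not on others. The adjusted Rand index with the reported clusters was 0.833 with either 1000 or 250 variable genes and 1 with genes detected in 2 or more cells. Without the members of the S phase and the G2 and M phase lists it was 0.915. Leading genes of cluster 1 outside those lists, such as Asf1b and Tk1, were not left out. This value therefore cannot show whether the split depends on the cell cycle. Average linkage also gave 2 clusters, but of other cells, with 2 cells in the smaller and an adjusted Rand index of 0.033. Without the 3 cells of extreme gene number the index was 0.518 and the silhouette 0.138, and with a pseudocount of 0.1, which gave 3 clusters, the index was 0.484.

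Cells E2-59 and E2-60, which share a position name, had a rho of 0.524 over genes, against a median of 0.478 for the 1081 pairs of cells. A higher rho was found in 89 pairs, and no columns were identical, so they were counted as separate cells. The letter of the cell name, A to H, explained a share of each measure examined that stayed under the upper end of the central 95% of 1000 random relabellings.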

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

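Of 268 values of 39 results recomputed under alternatives, 190 stayed within the spread defined for them. Alternatives without Ly6a, without cell D2, without S100a8 and S100a9, and the rescaling of median rho were chosen after seeing the data. The counts for Gfi1 (38 to 42 cells) stayed within their interval in every alternative run. Irf8 was detected in every cell kept, including 44 of 44 without cells of extreme gene number. Counts of cells with primary granule and monocyte genes also stayed within their interval, and primary granule genes stayed above monocyte genes in every cell. At TPM 10, 39 cells had at least 3 required surface genes, 40 had late granule and monocyte genes, and primary granule genes were found with dendritic genes in 21 cells and with basophil, mast cell and eosinophil genes in 1. With any value above 0, the dendritic count was 42. With 2 members per list, the counts with late granule and monocyte, stem, dendritic and basophil genes were 47, 27, 46 and 17, and with 5 members they were 26, 2, 2 and 0, because the requirement itself changed. Without Ly6a, an excluded surface gene was detected in 9 cells.

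Levels of lists with many zeros followed the pseudocount by construction. With 0.1, median levels were 0.76 for late granule, 2.56 for monocyte, -2.25 for stem, -2.86 for megakaryocyte and erythroid, -2.21 for basophil, -1.19 for dendritic, -2.07 for lymphoid and -1.60 for stromal genes. The primary granule minus monocyte difference was then 7.92, and clustering gave 3 clusters, for which the cause was not tested. With 10, the same lists had 5.16, 5.66, 3.63, 3.38, 3.59, 4.10, 4.02 and 3.54, G2 and M phase genes 4.33, and the difference was 5.10. With only members detected in 5 cells or more, fewer zeros entered, the lists had 5.93, 5.05, 1.45, 2.83, 2.33, 3.65, 11.52 and 1.99, and the difference was 5.47. The late granule minus monocyte difference then turned from -1.27 to 0.36, with 31 cells above 0. With the median of members, the monocyte level was 2.89, those of the other 7 lists were 0, the primary granule difference was 8.21, and 4 cells had late granule above monocyte genes. Without S100a8 and S100a9 that count was 3.

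For median rho, the cause of a change was not tested. Members in 5 cells or more gave 0.27 within late granule, 0.11 within stem and 0.39 within stress genes. Pearson's r gave -0.025 within stem, 0.49 within G2 and M phase, 0.19 within stress, and -0.11 between primary granule and S phase genes. Holding the number of genes detected constant gave 0.27 within S phase, 0.33 within G2 and M phase, and 0.074 between monocyte and S phase genes. Without cells B1, B4 and E7, whose numbers of genes were extreme, values were 0.051 within monocyte and 0.32 within stress genes. With E2-59 and E2-60 as 1 cell, stress genes had 0.18. Without cell D2, S phase genes had 0.36, and primary with late granule genes 0.13. Without S100a8 and S100a9, late granule genes had 0.13, and 0.14 when also rescaled. Rescaling gave 0.30 within primary granule, 0.32 within S phase, 0.17 within stress, 0.14 between primary and late granule, and 0.086 between monocyte and S phase genes. Primary granule with monocyte genes returned inside the random range in 3 alternatives, at percentiles 7.02, 11.5 and, rescaled, 3.94. Monocyte with stem genes, inside it at 2.94, left it at 0.26 with Pearson's r, 1.57 without cell D2 and 2.09 rescaled. That pair stayed inside at 35 with the number of genes detected held constant and at 17.9 without cells B1, B4 and E7. The percentile was 10.9 with only members detected in 5 cells or more, and 4.63 with E2-59 and E2-60 as 1 cell. Late granule with monocyte genes stayed below it in every alternative run. Depth is unknown, so a listed 0 cannot be told from a transcript missed in a cell.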

Other observations

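The tests on targeted-gene labels, on Ly6a with Ly6c levels and on the row letter were chosen after the result was seen. For median rho, holding the number of genes detected constant was chosen as an alternative before the results were seen. Its use to explain the relation of late granule to monocyte genes was chosen after. Of the stress list, Fos was detected in 42 cells at a median of 167 TPM, Jun and Ier2 in 33, Dusp1 in 24 and Egr1 in 22, while the heat shock genes Hspa1a and Hspa1b were detected in 2 and 6 and Atf3 in 0. The stress list had a median level of 2.97 and a median rho of 0.13 within it (percentile 99.6). That value was unstable, at 0.32 without cells B1, B4 and E7 and 0.39 with only members detected in 5 cells or more. Its median rho with S phase genes was -0.043 (percentile 0.01). Interferon response genes were low, at a median level of 0.63, with Stat1 in 30 cells, Irf7 in 13 and Isg15 in 4. Housekeeping genes had a median level of 9.93.

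Stem and multipotent genes had a median rho of -0.093 with S phase and -0.094 with G2 and M phase genes, both below all random lists. The rho of their levels was -0.37 with S phase and -0.22 with G2 and M phase genes when the number of genes detected was held constant. Basophil, mast cell and eosinophil genes had a median rho of 0.071 with primary granule genes (percentile 99.3) and -0.055 with monocyte genes (percentile 0.39). The genes of highest mean were Mpo, Elane, Actb, Eef1a1, Sod1, Gpx1, Plac8, Ubb, Ppia and Rps18. Those of largest excess variance included S100a9, Chil3, S100a8, Rrm2, Rps27, Gm15772, Hist1h2ao, Cd63 and Mrgpra2b. Ccl2, a monocyte chemoattractant gene among them, had a median of 1.14 TPM and reached 3331 TPM in cell A2. A Y-linked gene was detected in 44 cells and Xist in 0.

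Irf8 was detected in all 47 cells labelled as lacking it, and Gfi1 in 39. Reads borrowed from other genes argue poorly for this, since 1.93% of the 25-base stretches of Gfi1 transcripts and 0 of those of Irf8 occur in transcripts of other genes. Transcripts of targeted alleles that yield no protein may remain, and so may a wrong label. With 0 control groups and a single value per gene in the 47 cells, these cannot be told apart.

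Ly6a was detected in every cell of a Sca-1-negative sort. Reads shared with relatives are a candidate explanation, as 26.8% of the 25-base stretches of Ly6a transcripts occur in Ly6c1 or Ly6c2. Across cells, Ly6a had a rho of 0.72 with summed Ly6c1 and Ly6c2, above all 100 genes of like mean level. The same rho could come from neighbouring genes used together, and transcripts without surface protein were not tested.

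Late granule genes fell as monocyte genes rose across cells, with a pooled rho of levels of -0.39. Between single genes of the lists the median rho was -0.071. Without S100a8 and S100a9 and after rescaling it was -0.053 (percentile 0.65), so their share of TPM does not account for all of that median. Their part in the rho of levels was not tested. With the number of genes detected held constant, the median rho was -0.070 (percentile 0.01) and the rho of levels -0.32. Within letters of the cell name the mean rho of levels, weighted by the number of cells, was -0.42, over 8 letters of 4 to 8 cells, although it was above 0 in letters A and H. No biological explanation was tested, as the series has 1 group.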
